A study of Mus musculus with 4 samples.

How the data were processed

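The data were RNA-seq counts from 4 pools of E12.5 mouse neural tubes of the C57BL/6 background, 2 labelled WT and 2 labelled Lbx1Δ/Δ, each a pool of tubes of a single genotype from a single litter per the labels' protocols. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with the NEBNext Ultra RNA kit and sequencing was done on an Illumina HiSeq. Per the submitters' processing notes, TopHat2 2.1.1, featureCounts and edgeR were used with genome build mm9. The annotation, the strand setting, the aligner's options and the handling of reads shared by several transcripts are not given in the sources used here. The deposited values are raw counts of reads per RefSeq transcript, whole numbers with a different total in each library and no normalization, per the values of the files themselves.

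The 4 files held the same 41411 RefSeq accessions. Of these, 41218 were given a gene symbol from a RefSeq gene table of assembly GRCm38, 97 from the transcript table of a GENCODE annotation, and 96 stayed unnamed. The unnamed accessions were not left out, and each was treated as a gene of its own. GRCm38 is another build than mm9, so it was used only for names and for which genes neighbour each other, and no coordinates are given. The counts of a gene's accessions were summed, which gave 24971 genes, the unnamed accessions among them. Named accessions held 99.4%, 99.7%, 99.4% and 99.6% of the counts of WT libraries 1 and 2 and libraries 1 and 2 labelled mutant. The unnamed accession NR_046233 held 0.635%, 0.311%, 0.557% and 0.415% of them, and the 10 most abundant genes held 6.50%, 6.45%, 6.33% and 6.67%. Counting per transcript affected the values. Of 17047 genes with a single accession 41.3% had fewer than 10 counts in total, against 61.3% of 7924 genes with several, and Gapdh had 3 to 10 counts per library. Genes with several accessions may be counted in part only, so the values of Yeats2, Dvl1, Sirt3, Pafah1b1, Slc15a2, Il1rl1, 1700029J07Rik, Barhl1, Lhx2, Myl1, Ttn, Hoxa9, Hoxa10, Hoxd11, Gad1 and Slc17a6 are uncertain. Reads of overlapping, antisense or near-identical genes, such as Hox, globin or collagen paralogues, cannot be told apart further from the deposited counts.

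Symbols with low counts were removed with edgeR's filterByExpr by group at its defaults (a minimum count of 10 and a minimum total of 15), which left 10757 genes. TMM scaling, glmQLFit and glmQLFTest (edgeR 4.0.16 in R 4.3.3) tested genotype with no other covariate, two-sided, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. SE values are the log2 difference divided by the root of the F statistic. CPM per library were relative to the TMM-scaled total of the tested genes, and differences between libraries of the same replicate number were taken as log2 CPM with 0.5 counts added. Before the data were examined, 33 gene lists were written down from textbook markers of neural tube cell classes, of tissues a dissection could bring along, and of signalling pathways and stress. Lists with at least 3 tested members were tested with limma camera (limma 3.58.1) at the preset correlation of 0.01, two-sided, adjusted over the lists, with an estimated correlation and with fry as alternatives. Genes named in the text were chosen by a rule also written before the data were examined: Lbx1, up to 12 genes per direction past the threshold with an average log2 CPM above 1, or the 5 with the smallest p in a direction where fewer than 3 passed, and up to 4 members with the smallest p of each called or discussed list. The rule also let any member of the dorsal neuron lists be named, and a single gene that the rule picked is not reported here. Genes named outside the rule, such as Tubb3, Mki67, Hbb-bh1, Xist and Hoxc12, were chosen after their values were seen.

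Alternatives planned before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, edgeR's exact test, limma-voom, no low-count filter, a filter of CPM above 1 in 2 libraries, a fold minimum of 2, the replicate number as a block, and leaving out each library in turn. A fit limited to genes with a single accession was added after the data had been examined. With 1 library left in a group, its spread was taken to be that of the other group. The tests were tried on simulated counts for the 10757 genes. With no shift between numbers but with the spread of the fit on genotype alone, the genotype test recovered 2% of 2-fold and 47% of 4-fold changes. In that setting 2 unchanged genes were called. That spread includes the difference between numbers, so these shares do not show what the test would recover without such a difference. With numbers differing as in the data it recovered 0% of both, and the fit with the replicate block recovered 66% and 96%, with 10 unchanged genes called. In simulated lists of 10 genes, camera called the list shifted by 1 on the log2 scale (adjusted p = 2.52e-07) and 0 of the others. These lists held genes simulated independently of each other, with that same spread and no shift between numbers. They therefore do not show how often camera makes false calls on correlated genes. Comparisons of marker sets in the closing part used permutation tests with 100000 resamples or Fisher's exact test in SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Total counts of 16853984 to 20579803 per library leave genes with fewer than 10 counts imprecise.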

Results

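RNA was sequenced from neural tubes of E12.5 mouse embryos, a stage at which neurons of the dorsal spinal cord are being born. The 4 libraries comprised 2 labelled wild type (WT) and 2 labelled Lbx1Δ/Δ, and each library was made from a pool of tubes of a single genotype taken from a single litter. Total counts were 20579803 and 16948717 in WT libraries 1 and 2, and 17250143 and 16853984 in libraries 1 and 2 labelled Lbx1Δ/Δ. Counts had been deposited per RefSeq transcript and were summed here per gene symbol, and levels are given as CPM after TMM scaling of the library totals. A count of 0 allowed a level of up to 0.147 to 0.177 CPM (3 counts in the library), a bound that covers counting error only. The comparison addressed which transcripts differed between WT neural tubes and those carrying the Lbx1 mutation. The p-values measure the spread between these samples, which also differed by replicate number, so differences are also given within number 1 and within number 2.

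Lbx1, which encodes a homeodomain transcription factor of dorsal spinal cord interneurons, was at higher counts in the libraries labelled Lbx1Δ/Δ. Its counts were 819 and 1379 in WT libraries 1 and 2, and 1946 and 6520 in the libraries labelled mutant. The mean level was 60.9 ± 29.3 CPM (SD, n = 2) in WT and 248 ± 189 CPM (SD, n = 2) in the libraries labelled mutant, a fitted 4.07-fold ratio with a log2 difference of 2.02 (SE 0.68). Between libraries of the same number, the ratio was 2.83-fold for number 1 and 4.67-fold for number 2. The difference did not pass edgeR's quasi-likelihood test on genotype alone (unadjusted p = 0.0333, Benjamini-Hochberg adjusted p = 0.9998). The fitted log2 difference was 0.90 without library 2 labelled mutant. In the fit with the replicate number as a block it was 1.88 (SE 0.13, edgeR adjusted p = 1.19e-06), but the labels do not pair the numbers. A higher level of the targeted gene goes against the mutant label unless the counted part of the transcript lies outside the deletion. That alone would account for counts in the libraries labelled mutant, but not for counts above those of WT. The labels do not state which part was deleted and Lbx1 was counted as 1 transcript, so its counts do not check the genotype, and every direction given here is between libraries as labelled.

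**Figure D1:**
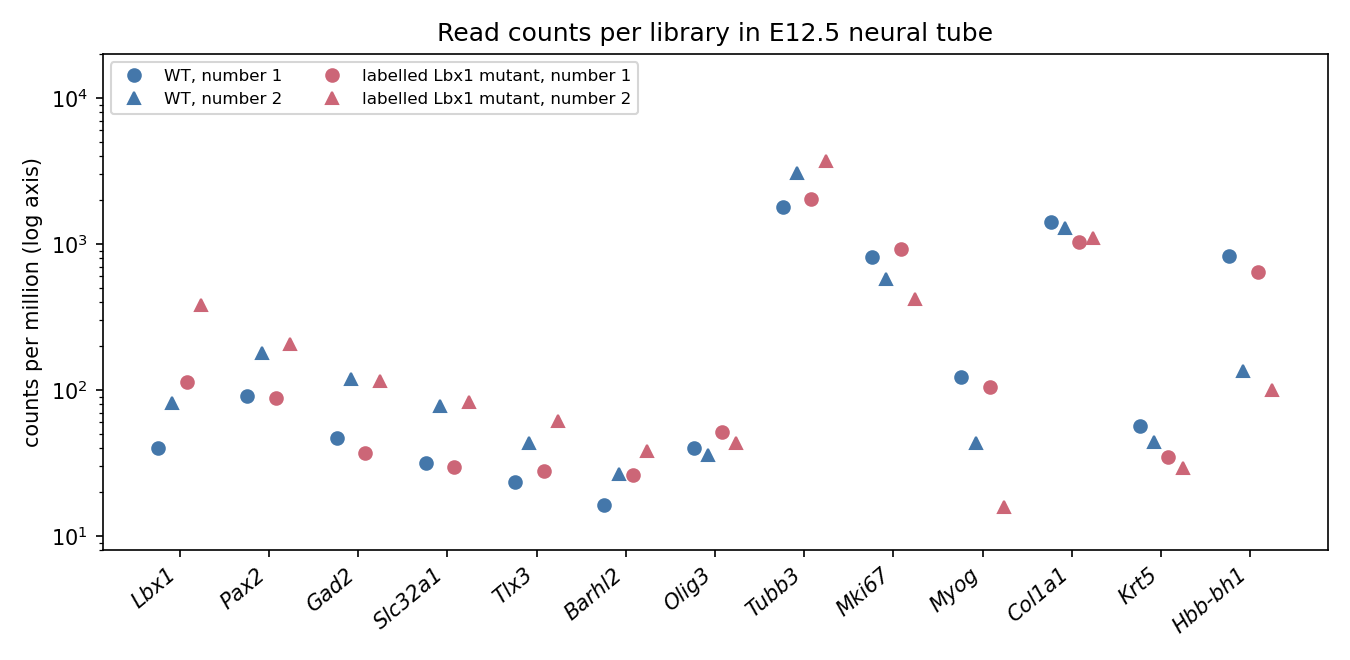
Level of 13 genes in each of the 4 libraries, in CPM on a logarithmic axis. Blue symbols are WT libraries and red symbols are libraries labelled Lbx1Δ/Δ, with circles for replicate number 1 and triangles for number 2. Lbx1 ran from 40.1 CPM in WT library 1 to 381 CPM in library 2 labelled mutant, while Hbb-bh1 and Mki67 were lower, and Tubb3 higher, in both libraries of number 2 than in both of number 1.

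Pax2, Gad2, Slc32a1 and Tlx3 are genes of dorsal interneurons that arise from Lbx1-expressing cells. In the fit on genotype alone, they differed between the groups by less than the standard error, which includes the difference between numbers. Pools of tubes do not tell these neurons apart from other cells that express the same genes. Pax2, a transcription factor of dorsal inhibitory interneurons, was at 135 ± 62.3 CPM (SD, n = 2) in WT and 147 ± 84.2 CPM (SD, n = 2) in the libraries labelled mutant, a log2 difference of 0.13 (SE 0.52). Gad2, which encodes a GABA-synthesising enzyme, had a log2 difference of −0.13 (SE 0.69), and Slc32a1, the vesicular transporter of GABA and glycine, one of 0.04 (SE 0.64). Tlx3, a transcription factor of dorsal glutamatergic neurons, was at 33.4 ± 14.1 CPM (SD, n = 2) in WT and 44.8 ± 24.0 CPM (SD, n = 2) in the libraries labelled mutant, a log2 difference of 0.42 (SE 0.50). All of these genes were higher in number 2 than in number 1 in both groups. With the numbers compared separately, Pax2 differed by −0.04 and 0.21, Gad2 by −0.34 and −0.06, and Tlx3 by 0.25 and 0.51 on the log2 scale. With the replicate number as a block, the log2 differences were 0.089 (SE 0.087) for Pax2 and −0.19 (SE 0.10) for Gad2. They were 0.0061 (SE 0.12) for Slc32a1 and 0.38 (SE 0.14) for Tlx3, all with an edgeR adjusted p of 0.268 or more.

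Of the 12 tested transcription factors of the dorsal GABAergic lineage, 7 had higher and 5 lower fitted values in the libraries labelled mutant. Their median log2 difference was 0.03 while their mean was −0.13, the direction that camera took (camera, adjusted p = 0.761). Dmrt3, a factor of dI6 interneurons, had counts of 89 and 90 in WT and 31 and 63 in the libraries labelled mutant (log2 −0.82, SE 0.47). Wt1, which also marks mesothelium and developing urogenital tissue, had counts of 436 and 129 in WT and 177 and 14 in the libraries labelled mutant (log2 −1.38, SE 1.17), a difference that was −4.12 without library 1 labelled mutant and −0.43 without WT library 1. Prdm13 and Bhlhe22 had log2 differences of 0.18 and 0.28. The 4 tested genes of GABA and glycine transmission had a median log2 difference of 0.11 (camera, adjusted p = 0.789), with 0.18 for Gad1. The 7 tested genes of dorsal glutamatergic neurons had a median of 0.21 (camera, adjusted p = 0.49), with 0.42 for Slc17a6, 0.21 for Pou4f1 and 0.30 for Lmx1b. The medians of this list within numbers 1 and 2 were 0.25 and 0.30, and 4 of the 7 members were higher within both. None of the members of these 3 lists passed the gene test by edgeR on genotype alone, over all genes or adjusted over the list alone (0 genes each). With the replicate block, 1 member, Wt1, was called lower (edgeR adjusted p = 0.0196). Leaving out WT library 1 or library 2 labelled mutant turned the log2 difference of Pax2 to −0.26 and −0.62.

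Genes of dorsal interneurons that do not express Lbx1 (classes dI1 to dI3) were higher as a group in the libraries labelled mutant. All 10 tested members had higher fitted values, and 6 were higher within both replicate numbers, with medians of 0.36 for number 1 and 0.29 for number 2 on the log2 scale. Camera gave an adjusted p of 0.000589 with its preset correlation and adjusted p = 0.81 with an estimated correlation. Barhl2, a homeobox factor of dI1 neurons, was at 21.4 ± 7.32 CPM (SD, n = 2) in WT and 32.2 ± 8.61 CPM (SD, n = 2) in the libraries labelled mutant, a log2 difference of 0.59 (SE 0.35). Barhl1 had counts of 14 and 6 in WT and 25 and 33 in the libraries labelled mutant (log2 1.68, SE 0.54), and is uncertain because it has several transcripts. Olig3, a factor of the dI1 to dI3 progenitors, was at 37.8 ± 2.97 CPM (SD, n = 2) and 47.6 ± 5.94 CPM (SD, n = 2), and Lhx2 had a log2 difference of 0.55 (SE 0.51), which was 0.010 without library 2 labelled mutant. The markers of mesenchyme, muscle and surface ectoderm had medians of −0.34, −0.55 and −0.47 in the same comparison, and those of ventral progenitors, motor neurons and neural progenitors had 0.28, 0.21 and 0.17. Pou4f1 is also in the list of glutamatergic neurons, Isl1 in that of motor neurons and Foxd3 in that of neural crest. The list is therefore not specific to the dI1 to dI3 classes. No member passed edgeR's gene test over all genes, and 0 passed adjusted over the list alone. The camera call was lost without WT library 1 (adjusted p = 0.16) and without library 2 labelled mutant (adjusted p = 0.0844).

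Genes of the Notch pathway, which keeps neural progenitors undifferentiated, were also higher as a group in the libraries labelled mutant. Of 9 tested genes, 8 had higher fitted values and the same 8 were higher within both numbers, with a median log2 difference of 0.20 (0.25 for number 1 and 0.15 for number 2). Camera gave an adjusted p of 0.00658 with its preset correlation and adjusted p = 0.81 with an estimated correlation. Lfng, a glycosyltransferase that modifies Notch receptors, was at 52.7 ± 2.64 CPM (SD, n = 2) in WT and 67.3 ± 1.08 CPM (SD, n = 2) in the libraries labelled mutant (log2 0.35, SE 0.17). Notch1 was at 261 ± 46.3 CPM (SD, n = 2) and 334 ± 25.1 CPM (SD, n = 2), and Hes5 and Dll3 had log2 differences of 0.49 and 0.31. Hes5 and Notch1 are also members of the neural progenitor list, whose median was 0.17. The mesenchyme, muscle and ectoderm lists, with medians of −0.34, −0.55 and −0.47, went the other way in the same libraries. No member passed edgeR's gene test over all genes, and 0 passed adjusted over the list alone. The camera call was lost without WT library 1 (adjusted p = 0.401), without library 1 labelled mutant (adjusted p = 0.219), without library 2 labelled mutant (adjusted p = 0.071) and without the low-count filter (adjusted p = 0.0647).

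Hox genes, whose combinations mark position along the body axis, were higher as groups in the libraries labelled mutant. Among paralogues 1 to 5 (hindbrain and cervical levels) 10 of 14 tested genes had higher fitted values, with a median log2 difference of 0.23, and among paralogues 6 to 9 (brachial and thoracic levels) 10 of 11 did, with a median of 0.24. Hoxd4 was at 72.7 ± 19.6 CPM (SD, n = 2) in WT and 100.2 ± 9.57 CPM (SD, n = 2) in the libraries labelled mutant (log2 0.46, SE 0.24), and Hoxa3, Hoxd3 and Hoxb4 had log2 differences of 0.31, 0.34 and 0.24. Hoxc6 was at 154 ± 10.4 CPM (SD, n = 2) and 182 ± 11.4 CPM (SD, n = 2), a log2 difference of 0.24 (SE 0.15). Hoxa6 and Hoxa7 had log2 differences of 0.80 and 0.27, and Hoxa9, uncertain because it has several transcripts, had counts of 5 and 6 in WT and 12 and 24 in the libraries labelled mutant. Camera gave adjusted p-values of 0.00918 for paralogues 1 to 5 and 0.00165 for paralogues 6 to 9 with its preset correlation, and adjusted p = 0.81 for both with an estimated correlation. Lower medians of mesenchyme (−0.34), muscle (−0.55) and ectoderm (−0.47) genes went with these Hox values. Within number 1 the medians were 0.34 and 0.31, and within number 2 they were 0.12 and 0.24. No member of either list passed edgeR's gene test on genotype alone over all genes, and 0 passed adjusted over the list alone. With the replicate block, Hoxd4, Hoxa6 and Hoxb6 were called higher (edgeR adjusted p = 0.0354, 0.0246 and 0.0283). Without WT library 1 camera turned both lists to lower (adjusted p = 0.902 and 0.988). Without library 2 labelled mutant it lost paralogues 1 to 5 (adjusted p = 0.218) and turned paralogues 6 to 9 (adjusted p = 0.779), and without the low-count filter it lost paralogues 1 to 5 (adjusted p = 0.0918).

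Paralogues 10 to 13, the lumbosacral Hox genes, went opposite ways in the separate replicate numbers. Their median log2 difference was 3.15 for number 1 and −0.45 for number 2, and 1 of the 10 tested genes was higher within both numbers. Hoxd13 had counts of 8 and 66 in WT and 97 and 25 in the libraries labelled mutant, and Hoxd11 had 7 and 86 in WT and 59 and 59 in the libraries labelled mutant. Hoxa11 had counts of 68 and 329 in WT and 136 and 179 in the libraries labelled mutant, and Hoxa10 had a log2 difference of 0.54. WT library 1 thus held few of these transcripts, with 0 counts of Hoxc12 against 183, 61 and 156 in WT library 2 and libraries 1 and 2 labelled mutant, and the median for number 1 was also 3.15 with Hoxc12 in WT library 1 set to its bound of 3 counts. Over all 4 libraries 6 members had higher fitted values, with a median of 0.23 (camera, adjusted p = 0.0483, with 0.0509 under RLE scaling, 0.117 without the low-count filter and adjusted p = 0.81 with an estimated correlation). Leaving out WT library 1 turned the call to lower (camera, adjusted p = 7.53e-05), and the call was lost without library 1 (adjusted p = 0.0797) or library 2 (adjusted p = 0.0582) labelled mutant. No member passed edgeR's gene test over all genes, and 0 passed adjusted over the list alone.

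Genes of mesenchyme and cartilage, of skeletal muscle and of surface ectoderm were lower as groups in the libraries labelled mutant. Of 13 tested genes of mesenchyme and cartilage 12 had lower fitted values, 10 of them within both numbers, with a median log2 difference of −0.34 (camera, adjusted p = 0.000173, and adjusted p = 0.81 with an estimated correlation). Matn1, a cartilage matrix protein, was at 3.60 ± 0.593 CPM (SD, n = 2) in WT and 1.26 ± 0.209 CPM (SD, n = 2) in the libraries labelled mutant (log2 −1.51, SE 0.40). Col1a1, a collagen of connective tissue, was at 1350 ± 77.8 CPM (SD, n = 2) and 1065 ± 51.4 CPM (SD, n = 2), and Col1a2 and Col3a1 had log2 differences of −0.37 and −0.34. Within numbers 1 and 2 the list medians were −0.20 and −0.29. The camera call was lost without WT library 1 (adjusted p = 0.22) and without library 2 labelled mutant (adjusted p = 0.507). No member passed edgeR's gene test over all genes, and 0 passed adjusted over the list alone.

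Skeletal muscle genes had a median log2 difference of −0.55, and 10 of the 11 tested had lower fitted values, 9 of them within both numbers (camera, adjusted p = 0.000332, and adjusted p = 0.81 with an estimated correlation). The size differed between numbers, with a median of −0.23 for number 1 and −1.57 for number 2, the latter also with members at 0 counts set to their bound. Myh3, the embryonic myosin heavy chain, was at 332 and 174 CPM in WT libraries 1 and 2 and at 283 and 53.4 CPM in the libraries labelled mutant. Myl1 and Chrna1 had log2 differences of −0.73 (SE 0.65) and −0.78 (SE 0.74), which were −0.11 and −0.10 without library 2 labelled mutant. Ttn, uncertain because it has several transcripts, had counts of 30 and 11 in WT and 17 and 0 in the libraries labelled mutant. Without library 2 labelled mutant camera turned the list to higher (adjusted p = 0.0909), and without WT library 1 the call was lost (adjusted p = 0.22). Genes of surface ectoderm and epithelium were lower in 6 of 6 tested members, 4 of them within both numbers, with a median log2 difference of −0.47 (camera, adjusted p = 0.00579, and adjusted p = 0.81 with an estimated correlation). Krt5, a keratin of basal epithelial cells, was at 50.1 ± 8.69 CPM (SD, n = 2) in WT and 32.1 ± 3.82 CPM (SD, n = 2) in the libraries labelled mutant, and Epcam, Krt15 and Krt18 had log2 differences of −0.60, −0.34 and −0.67. The list medians were −0.32 for number 1 and −0.84 for number 2, and camera turned the list to higher without library 2 labelled mutant (adjusted p = 0.795) and lost it without WT library 1 (adjusted p = 0.737). No member of the muscle or ectoderm list passed edgeR's gene test on genotype alone over all genes, and 0 passed adjusted over the list alone. With the replicate block, Myh3 and Krt5 were called lower (edgeR adjusted p = 0.047 and 0.042).

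**Figure D2:**
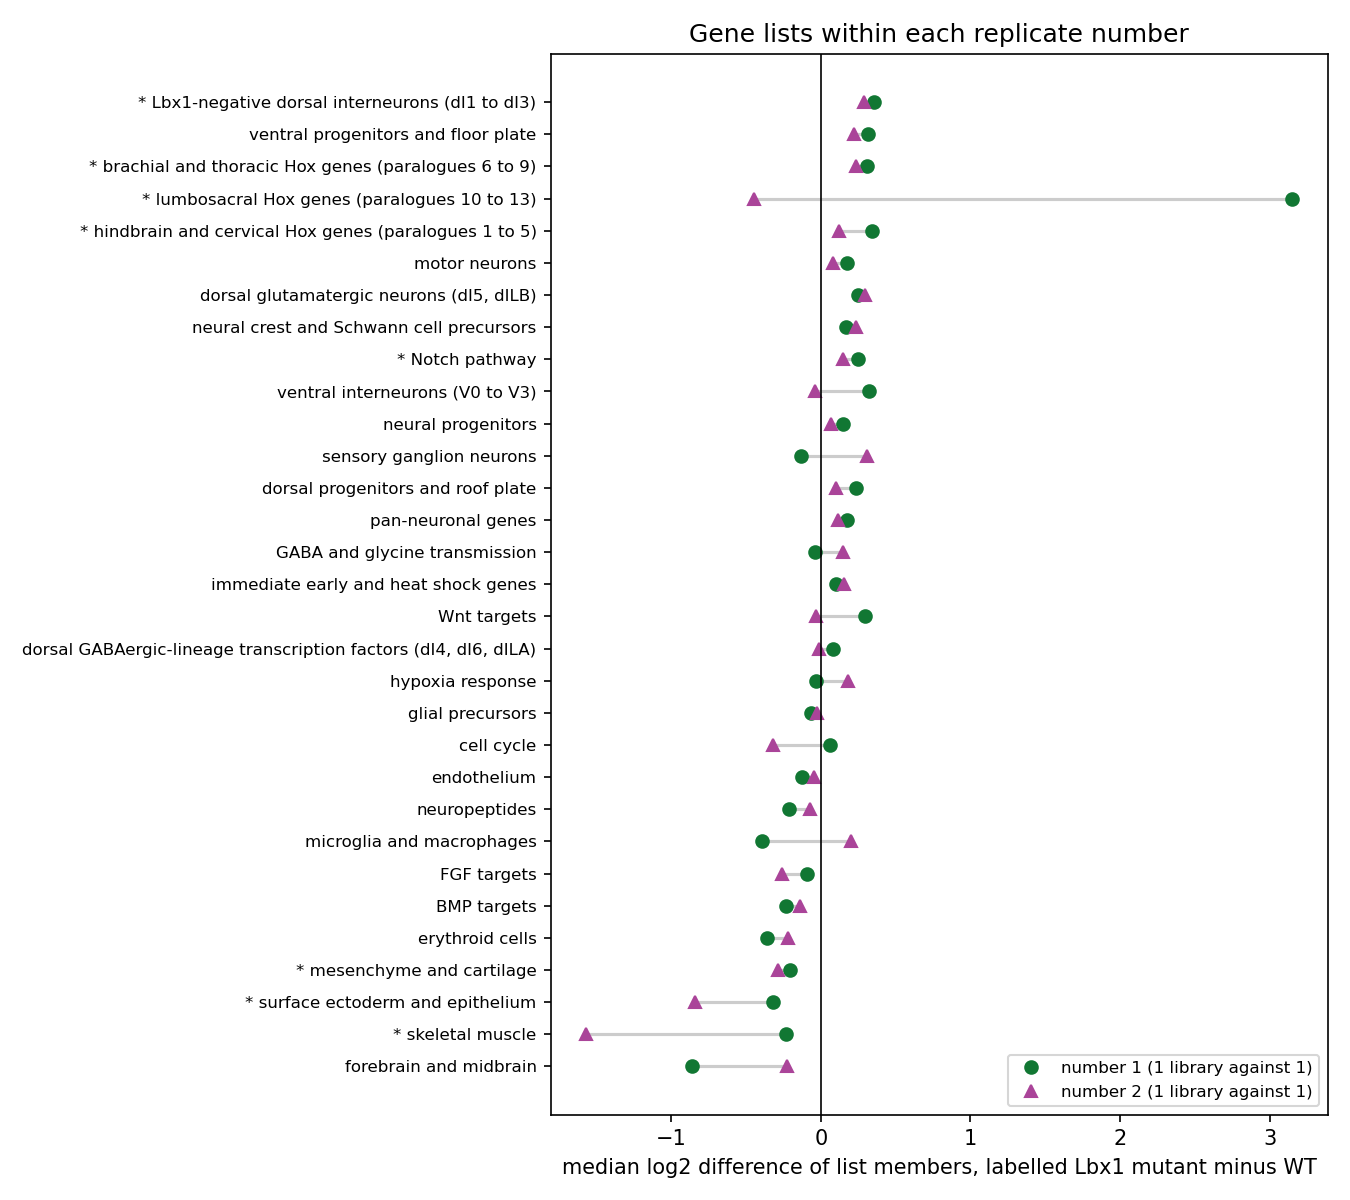
Median log2 difference between the library labelled Lbx1Δ/Δ and the WT library of the same replicate number, for the tested members of 31 gene lists, with green circles for number 1 and purple triangles for number 2. Asterisks mark lists with a camera adjusted p below 0.05 at the preset correlation. The medians of the mesenchyme list (−0.20 and −0.29) and of the dI1 to dI3 list (0.36 and 0.29) lie close together, while those of the lumbosacral Hox list (3.15 and −0.45) lie on opposite sides of 0.

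Of 10757 genes tested singly, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 55 had an unadjusted p below 0.05. DESeq2, edgeR's exact test and limma-voom, also run on genotype alone, called 0 genes, with 33, 60 and 61 at an unadjusted p below 0.05. The edgeR fit with the replicate number as a block called 92 genes, 29 higher and 63 lower in the libraries labelled mutant. The labels do not state that block, and its calls are given in the closing part. Among genes with higher values in the libraries labelled mutant, the 5 smallest p-values belonged to Yeats2, Dvl1, Gm5086, Pafah1b1 and Sirt3. Pafah1b1, a regulator of the dynein motor in migrating neurons, was at 11.8 ± 0.768 CPM (SD, n = 2) in WT and 26.4 ± 8.15 CPM (SD, n = 2) in the libraries labelled mutant (log2 1.16, SE 0.30). The other 4 had at most 22 counts in any library. Pafah1b1, Yeats2, Dvl1 and Sirt3 have several transcripts, so their counts are uncertain. Among genes with lower values the 5 were Slc15a2, Il1rl1, Atp6ap1l, Ide and 1700029J07Rik. Slc15a2, a peptide transporter, was at 16.9 ± 1.57 CPM (SD, n = 2) in WT and 5.76 ± 1.46 CPM (SD, n = 2) in the libraries labelled mutant, a log2 difference of −1.56 (SE 0.31) with the smallest unadjusted p of all (0.00464). Ide, the insulin-degrading enzyme, whose gene lies on the chromosome of Lbx1, was at 231 ± 44.5 CPM (SD, n = 2) and 133 ± 15.7 CPM (SD, n = 2), a log2 difference of −0.80 (SE 0.21). Il1rl1, Atp6ap1l and 1700029J07Rik had at most 29 counts in any library. Slc15a2, Il1rl1 and 1700029J07Rik have several transcripts, so their counts are uncertain. In counts simulated for these 10757 genes with the observed difference between numbers, the genotype test recovered 0% of 2-fold and 0% of 4-fold changes. A count of 0 called genes therefore does not show that expression was alike.

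Of the 33 gene lists, 32 had enough tested members for camera, and the 8 described above passed, 5 higher and 3 lower in the libraries labelled mutant. With an estimated correlation camera called 0 lists, and fry called 0. The lists that did not pass included the other neuron and progenitor classes of the neural tube. Median log2 differences were 0.15 for dorsal progenitors and roof plate (camera, adjusted p = 0.278), 0.28 for ventral progenitors and floor plate (adjusted p = 0.236), 0.17 for ventral interneurons (adjusted p = 0.288) and 0.21 for motor neurons (adjusted p = 0.146). Neural progenitor genes had a median of 0.17 (camera, adjusted p = 0.0702), pan-neuronal genes 0.12 with 7 of 7 higher (adjusted p = 0.278), glial precursor genes 0.00 (adjusted p = 0.664) and neuropeptide genes −0.15 (adjusted p = 0.848). Cell cycle genes had a median of −0.07 (camera, adjusted p = 0.335). Among tissues near the tube, medians were 0.16 for sensory ganglion neurons (camera, adjusted p = 0.789), 0.20 for neural crest and Schwann cell precursors (adjusted p = 0.457), −0.10 for endothelium (adjusted p = 0.49), −0.33 for erythroid cells with 5 of 5 lower (adjusted p = 0.359), −0.17 for microglia and macrophages (adjusted p = 0.439) and −0.72 for forebrain and midbrain genes with 5 of 5 lower (adjusted p = 0.251). Among pathway and stress lists, medians were 0.03 for hypoxia (camera, adjusted p = 0.789), 0.09 for immediate early and heat shock genes (adjusted p = 0.272), −0.17 for FGF targets (adjusted p = 0.227), 0.06 for Wnt targets (adjusted p = 0.359) and −0.23 for BMP targets (adjusted p = 0.251). Hedgehog targets had 2 tested members, too few for camera, with a median of 0.03. Xist and the Y-linked genes had a median of −1.58 over 3 tested genes (camera, adjusted p = 0.278). No gene of these lists passed edgeR's test on genotype alone over all genes, and 0 passed adjusted over the list alone. With the replicate block, the pan-neuronal gene Map2 was called higher and the glial precursor gene Tnc lower (edgeR adjusted p = 0.0177 and 0.00383).

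The replicate number went with larger differences than the genotype label. Tubb3, a tubulin of neurons, had 36338 and 34859 counts in WT library 1 and library 1 labelled mutant, and 51655 and 63161 in those of number 2. Mki67, a marker of dividing cells, had 16719 and 15766 counts in the libraries of number 1 and 9746 and 7152 in those of number 2, and Hbb-bh1, an embryonic globin, had 16872 and 11020 against 2287 and 1717. Between numbers, 1316 genes differed by over 1 on the log2 scale among the WT libraries and 1888 among those labelled mutant, while between the groups 552 genes did so within number 1 and 675 within number 2. The first principal component held 70.6% of the variance and placed both libraries of number 1 (scores −39.3 and −30.2) apart from those of number 2 (22.3 and 47.2). Both libraries labelled mutant lay on the same side of both WT libraries in 2208 genes, or 20.5%. The share would be 33.3% if all orders of the libraries were equally likely. As libraries of the same number resembled each other, 33.3% is not a baseline for the genotype label, and the share expected without a genotype effect is not known. Xist counts were 2 and 15267 in WT libraries 1 and 2 and 19495 and 10253 in the libraries labelled mutant, and those of the Y-linked gene Ddx3y were 2019, 376, 0 and 556 in the same order. WT library 1 thus had the counts of male embryos, library 1 labelled mutant those of female embryos, and both libraries of number 2 had both transcripts.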

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

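The alternatives here were planned before the data were examined, except the fit on genes with a single accession. The count of 0 called genes was also 0 with RLE and upper-quartile scaling, DESeq2, edgeR's exact test, limma-voom, either other low-count filter, single-accession genes and each library left out. With the replicate block it was 92 genes, 29 higher and 63 lower in the libraries labelled mutant, and the log2 difference of Lbx1 was 1.88 (SE 0.13, edgeR adjusted p = 1.19e-06, against 0.873 or more in each other alternative). The labels do not say that WT and mutant pools of the same number share a litter, so the block rests on a hint from the data: deviations of same-numbered libraries from their group means correlated at 0.66 across genes, and the biological coefficient of variation was 0.307 without and 0.110 with the block. The log2 difference of Lbx1 ran from 0.90 to 2.66 with a library left out. Camera called 0 lists with an estimated correlation, 0 by fry (smallest adjusted p = 0.954) and 14 in the fit with the replicate block (0 there with an estimated correlation), and 3 to 15 with a library left out (3 without WT library 1, 15 without WT library 2 and 15 without library 1 labelled mutant). The value of Hoxa11 turned to 0.23 with limma-voom and to 0.054 with the replicate block.

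Of 55 named genes, 19 changed sign with some library left out, which leaves 3 libraries. The log2 differences of neuronal genes then ran from −0.62 to 0.70 for Pax2, −0.71 to 1.01 for Gad1, −1.17 to 0.69 for Gad2, −0.88 to 0.82 for Slc32a1, −0.27 to 0.93 for Tlx3, −0.33 to 1.30 for Slc17a6, −0.39 to 0.68 for Pou4f1, −0.76 to 1.33 for Lmx1b and −0.069 to 0.61 for Bhlhe22. Those of muscle and epithelial genes ran from −2.23 to 0.16 for Myh3, −1.53 to 0.14 for Epcam, −0.93 to 0.074 for Krt15 and −2.19 to 0.56 for Krt18. Those of Hox genes ran from −0.063 to 1.42 for Hoxa6, −0.12 to 0.59 for Hoxa7, −0.077 to 1.05 for Hoxa10, −1.06 to 1.46 for Hoxa11, −0.55 to 3.30 for Hoxd11 and −0.52 to 3.16 for Hoxd13. A further 19 named genes, Lbx1 among them, kept their sign but moved by over 1.5 times. The others ran from 0.28 to 0.98 for Barhl2, 0.010 to 0.96 for Lhx2, 0.21 to 0.45 for Olig3, −4.12 to −0.43 for Wt1, −1.42 to −0.38 for Dmrt3, 0.082 to 0.28 for Prdm13, −1.81 to −0.11 for Myl1, −2.09 to −0.10 for Chrna1, −0.58 to −0.12 for Col1a2, −0.58 to −0.051 for Col3a1, 0.23 to 0.77 for Hoxd4, 0.15 to 0.49 for Hoxa3, 0.075 to 0.68 for Hoxd3, 0.040 to 0.48 for Hoxb4, 0.23 to 0.82 for Hes5, 0.20 to 0.55 for Notch1 and 0.096 to 0.58 for Dll3, and the last was Ttn, at 0 counts in a library. Camera's adjusted p for lists that turned direction ran from 3.09e-18 to 0.22 for muscle, 4.92e-05 to 0.795 for surface ectoderm, 0.000138 to 0.902 for Hox paralogues 1 to 5, 5.43e-06 to 0.988 for paralogues 6 to 9 and 1.08e-14 to 0.0797 for paralogues 10 to 13. The cause of these changes was not tested. Genes with few counts, such as Yeats2 with 2 counts in each WT library, rest on few reads, and the share of depth and of counting per transcript in this was not separated.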

Other observations

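All tests of explanations in this part were chosen after the results were seen, except the odds ratio for DNA flanking the targeted locus. Libraries of number 2 held more neuronal and fewer mitotic, blood and rostral transcripts than those of number 1 under both labels. Median log2 differences, number 2 minus number 1, were 0.92 in WT and 0.86 in the libraries labelled mutant for pan-neuronal genes, 1.34 and 1.55 for GABA and glycine transmission, −1.98 and −1.85 for erythroid genes, and −2.63 and −1.56 for forebrain and midbrain genes. In the same order, they were −0.93 and −2.61 for skeletal muscle, −0.77 and −1.37 for surface ectoderm, and −0.49 and −0.47 for mesenchyme and cartilage. Emx2, a forebrain transcription factor, had 518 and 34 counts in WT libraries 1 and 2 and 333 and 6 in the libraries labelled mutant. Ttr, a gene of choroid plexus, had 2920, 263, 622 and 15 in the same order. With genotype in the edgeR fit, 3833 genes differed between numbers, 1914 higher and 1919 lower in number 2.

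Genes that edgeR called with the replicate block are given as a hypothesis, since the labels do not pair the numbers, and were picked from the calls after their values were seen. Higher calls in the libraries labelled mutant included neuronal genes, though of the 7 tested genes of the pan-neuronal list 1 was called higher. Uncx and Otp, homeobox factors of neurons, had log2 differences of 0.78 and 0.79 (Benjamini-Hochberg adjusted p = 0.00554 and 0.0139), and Robo3, a guidance receptor of commissural axons, had 0.56 (adjusted p = 0.0102). The smallest edgeR adjusted p-values among lower calls were those of Ttr (log2 −2.52, adjusted p = 0.00044) and Slc15a2 (log2 −1.57, adjusted p = 0.00264). Clic6 and the mesenchymal gene Ogn followed (log2 −1.68 and −1.12, adjusted p = 0.00347 for both). Other lower calls included the mesenchymal genes Six2 and Tbx15, 5 collagen genes and the muscle myosin Myh3 (log2 −0.94, adjusted p = 0.047). Of the 13 tested genes of the mesenchyme and cartilage list, 1 was called lower, Lum (log2 −0.44, edgeR adjusted p = 0.0275).

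The resemblance of libraries of the same number is open to several explanations. Library depth is argued against, since the libraries labelled mutant, whose totals differed by 2.35%, had 1888 genes over 2-fold apart, against 1316 for the WT libraries, whose totals differed by 21.4%. Sex is argued against as the whole cause, since WT library 1 and library 1 labelled mutant, of opposite sex by Xist and Ddx3y, correlated at 0.987 across genes, against 0.972 for both WT libraries. A later stage or other tissue proportions in number 2 may be the source and stays open: pan-neuronal, cell cycle and erythroid medians all moved by 0.64 or more on the log2 scale under both labels, but these classes had been seen to differ before the explanation was put forward, so this does not decide it.

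The higher counts of Lbx1 in the libraries labelled mutant could come from more cells of its lineage, from a higher level of transcripts of the deleted allele, or from exchanged labels. Counts from outside the deletion would not by themselves exceed those of WT. More cells that express the lineage's other genes, in step with Lbx1, are argued against, since the upper quartile of 19 such genes differed by 0.19 on the log2 scale (highest 0.46). Lbx1 itself differed 2.83-fold within number 1 and 4.67-fold within number 2. Cells outside the lineage that express these genes would make such a rise look smaller, by an amount that was not tested. More cells of the lineage that lack these transcripts stay open, because the 19 genes cannot count them. Transcripts of the deleted allele cannot be told apart from intact ones, because Lbx1 has 1 accession and no counts per exon. Exchanged labels cannot be excluded either, since the median of the dorsal GABAergic factors was 0.031 with members on both sides of 0.

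The lower mesenchyme, muscle and ectoderm genes in the libraries labelled mutant may reflect dissection as well as genotype. Less of every surrounding tissue alike stays open: the median of 11 muscle genes minus that of 14 sensory ganglion and crest genes was −1.01 on the log2 scale, but −0.27 within number 1 and −1.84 within number 2 (permutation tests over genes, which are not independent, two-sided, p = 0.141 and 0.00026), so the gap rests mainly on number 2. A direct effect of DNA flanking the targeted locus is argued against for 86 of the 91 genes other than Lbx1 called with the replicate block, which lie on other chromosomes, and stays open for Ide, Ahnak, Pgm5, Slit1 and Acta2 (odds ratio 1.64 of lying on that chromosome, one-sided Fisher's exact p = 0.203), while 0 of the 10 nearest tested neighbours of Lbx1 were called. Of the 92 called genes, 92.4% differed between numbers in the direction of their genotype difference under both labels, against 53.2% of all tested genes. Pools labelled mutant that lie further along the difference between numbers, in stage or tissue content, are thus a candidate explanation, tissue content stays open in the same way for the higher dI1 to dI3, Notch and Hox lists, and an effect of the genotype on these genes stays open and was not separated from it.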
